A study of Caenorhabditis elegans with 4 samples.

How the data were processed

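Chromatin bound by RNA polymerase II (Pol II) was immunoprecipitated from third-stage (L3) hermaphrodite larvae of the Caenorhabditis elegans strain OP26 and sequenced together with input DNA, which is the same kind of chromatin without the precipitation step. Strain OP26 carries the transgene wgIs26, a copy of the Hox gene mab-5 fused to GFP, beside a copy of unc-119 that rescues the host's unc-119 mutation. Per the labels, the worms were grown in liquid culture at 20 degrees Celsius and crosslinked in 2% formaldehyde, and the Pol II libraries were made with the mouse monoclonal antibody 8WG16, which binds the C-terminal repeats of the largest Pol II subunit. The shared protocol text of the same labels describes a precipitation with anti-GFP serum from embryos, so it differs from the sample descriptions in both the antibody and the stage. The sample descriptions and stage labels were followed here. There were 4 libraries: 2 of input DNA and 2 of Pol II chromatin, from 2 numbered extractions.

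A single peak list was analysed. Its name says that it combines the libraries, and it holds no column for a single library. Peaks were called with PeakSeq, which compares read counts in candidate regions between precipitated and input libraries, per the file's source field. The genome build was WormBase WS180, per the file headers. The aligner, the read filters, the way in which replicates were combined and the PeakSeq version are not given in the sources used here. The authors deposited a q-value for each peak, that is, a p-value adjusted for the number of regions tested. The other values are the deposited first and last base of each peak, counted from 1. The q-value in the score field equalled that in the attribute field for all 5942 peaks, the largest q-value was 0.0099, and no gap between neighbouring peaks was shorter than 200 bp. No read counts are given, so the depth per library is unknown, and no interval that needs it was computed. Every q-value comes from the pooled libraries, so no value here has an error between replicates.

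Peak width, peak midpoint and −log10 of the q-value were computed from the list. Each chromosome was divided into windows of 1 Mb from its first base, and only the 97 windows that ended before the last listed peak of their chromosome were used for means over windows, because chromosome lengths of that build were not used here. Peaks were counted by midpoint. Windows with their midpoint in the central 50% of the stretch up to the last peak were called centre, and the others arms. The X chromosome was compared with the autosomes, and centres with arms (labels exchanged within chromosomes), by two-sided permutation tests over windows with 100000 resamples. Tests within 1 chromosome enumerated all splits, with Benjamini-Hochberg adjustment over the 6 chromosomes. A permutation p measures the spread between regions of 1 pooled list, not between worm cultures, and neighbouring windows are not independent. Width and −log10 q were related across peaks by Spearman's rho and by Pearson's r on log values, with permutation p. Spacing was compared with 1000 random placements of the same peaks on their chromosomes with gaps of at least 200 bp. Intervals of medians are 95% bootstrap intervals from 1000 resamplings of windows, the partial last window of each chromosome included. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

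The procedures were tested on simulated data. For the comparison of X with autosomes over 97 windows, 85.5% of 200 simulated differences of 1.5-fold were called and 4% of unchanged sets. For centres against arms over 80 windows, the shares were 96% and 4.5%. These windows were drawn independently around a common mean, that of chromosome II, and X or the centres were raised. In the data, the autosomes differ in mean, X was lower than the pooled autosomes and neighbouring windows are not independent. The shares therefore describe the procedures in that simpler setting, not the tests on this list. For spacing on chromosome II, 100% of 40 sets with added neighbours and 5% of 40 uniform sets were called.

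The tests, the groups and the rule for named peaks were fixed before the data were examined. Without gene names, that rule took the 10 peaks with the smallest q-value, the 5 widest peaks, the peak with the smallest q-value on each chromosome and the longest runs of windows with and without peaks. Several analyses were added after the data were seen. For chromosome I, these were the comparisons with the other autosomes and with III, the comparison of −log10 q in bins of width, and random placement before merging. For chromosome I and the other results, they were the tests within single chromosomes, the values without single chromosomes, merging within 1 kb or 5 kb, the rotation of window profiles, the mean of the log2 ratios of the autosomes and placement within windows. The recovery of ranks from the q-values, the placing of higher ranks on X or in the arms, the longest gaps in bases and the tests in the observations were also added then. Peaks were not assigned to genes. The gene table at hand describes the assembly WBcel235 rather than WS180, the list names no gene, and coordinates of different builds were not combined. The planned comparisons with gene starts and bodies, fixed gene lists and GC content were therefore not run.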

Results

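Pol II occupancy was profiled by ChIP-seq in L3 larvae that carry a MAB-5::GFP transgene. MAB-5 is a Hox transcription factor that patterns the posterior body, and the precipitated protein was Pol II itself, whose largest subunit is encoded by ama-1. The pooled list held 5942 Pol II peaks from 2 Pol II and 2 input libraries. The peaks covered 8.00 Mb, or 7.99% of the 100.1 Mb up to the last peak of each of the 6 chromosomes. The median width was 611 bp, with quartiles of 282 and 1446 bp, and the widest peak spanned 23456 bp. There were 329 peaks of 5 kb or more and 361 peaks of 50 bp or less, of which 21 were 1 bp wide. A q-value of 1e-20 or less was reached by 1294 peaks. The depth of the libraries is unknown, and the values below have no replicate error, because the list gives none per library.

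The q-values imply the rank of each region in the calling. A q-value of this kind is the p-value times the number of regions tested, divided by the rank. Taking the first listed peak as rank 96 made 686 neighbouring peaks equal in p to within a relative 1e-11, with 0 falls in the recovered p-values along the list. The 0 falls alone would also hold for any first rank smaller than 96. None of the other 299 first ranks tried gave an equal pair. The p-values of the 10 peaks at the top were single digits times a power of 10 only if 19411 regions had been tested, of all numbers up to 60000. The list therefore ran from rank 96 to rank 6037, and the 95 regions of higher rank, 1.57% of the ranks up to 6037, were not analysed here.

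The listed peaks with the smallest q-values, called strongest here, lay on all autosomes. A smaller q-value need not mean a stronger enrichment, for which the list holds no value. Of the 10 peaks with the smallest q-values, 4 were on chromosome V, 3 on I, 1 on II, 1 on III, 1 on IV and 0 on X. Their widths ranged from 2878 to 15467 bp. The smallest q-value, 2.02e-306, belonged to a peak on chromosome V from 11828841 to 11832166 (WS180, as are all positions). It was followed by a peak on chromosome IV from 13388415 to 13395692 (q = 2e-304), which was also the strongest of that chromosome, and by one on chromosome II from 11268300 to 11272346 (q = 3.96e-304). The other peaks of this group on chromosome V lay at 1149683 to 1159041 (q = 7.84e-303), 5838454 to 5847514 (q = 1.73e-300) and 11528987 to 11542024 (q = 1.87e-297). Those on chromosome I lay at 7378952 to 7383112 (q = 9.71e-302), 3652341 to 3656634 (q = 1.88e-299) and 9332323 to 9335200 (q = 1.85e-294). The strongest peak of chromosome III reached from 4491055 to 4506521 (q = 1.9e-299). On X the strongest peak lay at 17419161 to 17421987, with a q-value of 1.67e-282. These are the strongest peaks of the listed ranks only.

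None of the 5 widest listed peaks was among the 10 strongest listed. Regions of higher rank than the list could be in neither group, and their widths are unknown. A peak of 23456 bp on chromosome V, from 14828205 to 14851660, had a q-value of 3.84e-103. On X, a peak of 22089 bp reached from 11464320 to 11486408 (q = 7.76e-31) and one of 20216 bp from 3816052 to 3836267 (q = 6.31e-161). The remaining peaks of this group were 20810 bp on chromosome II, from 3952228 to 3973037 (q = 1.05e-31), and 18926 bp on chromosome V, from 20396896 to 20415821 (q = 1.19e-194).

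Chromosome I held the most Pol II peaks. It carried 2178 peaks, 36.7% of the list on 15.03% of the analysed length. Chromosome IV had 912 peaks, III had 901, II had 713, V had 633 and X had 605. Per 1 Mb window, chromosome I had 145 ± 36.0 peaks (mean and SD over 15 windows), against 46.9 ± 26.7 over the 65 windows of the other autosomes. This difference of 3.09-fold had a permutation p of 1e-05, the smallest that the resampling can give. The comparison was made because chromosome I had the most peaks, and as 1 of 5 autosomes it cannot reach a one-sided p below 0.2 in an exact permutation of chromosomes. The autosome next in density, III, had 65.5 ± 21.9985 peaks per Mb (13 windows), so that chromosome I was 2.21-fold above it (permutation p = 1e-05). After peaks within 5 kb of each other had been merged, the difference was 1.52-fold (41.6 against 27.4 merged regions per Mb, permutation p = 0.0001), and against the 34.4 merged regions per Mb of III it was 1.21-fold (permutation p = 0.035). Placing the peaks of each chromosome at random before merging gave 1.80-fold (95% of 100 placements between 1.74 and 1.85). With 1 kb as the limit, the difference was 2.34-fold (permutation p = 1e-05), and random placement gave 2.83-fold (2.78 to 2.87). The bases covered differed less than the peak number, at 110 ± 24.0 kb per Mb on chromosome I against 76.9 ± 33.0 kb (1.43-fold, permutation p = 0.00034). Chromosome III had 92.5 ± 32.8 kb per Mb, from which chromosome I did not differ by more than the spread between windows (1.19-fold, permutation p = 0.11). Peaks on chromosome I were also narrower, with a median of 421 bp (95% interval 406 to 447) against medians between 640 bp on III and 995 bp on X.

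The X chromosome had fewer peaks per Mb than the pooled autosomes, but the call was lost without chromosome I and after wide merging. Windows of X held 33.6 ± 12.4 peaks (17 windows) and those of the 5 autosomes 65.3 ± 47.8 (80 windows), a log2 ratio of -0.96 (permutation p = 0.0086). Without chromosome I the autosomes had 46.9 ± 26.7 peaks per Mb, the log2 ratio was -0.48 and the permutation p was 0.052. With all autosomes but peaks within 5 kb merged, X had 24.4 regions per Mb against 30.1 (log2 ratio -0.30, permutation p = 0.094). Chromosome V, at 30.4 ± 22.8 peaks per Mb over 20 windows, lay below X. In covered bases, X had 63.997 ± 18.7 kb per Mb and the autosomes 83.2 ± 34.0 kb (log2 ratio -0.38, permutation p = 0.026). Without chromosome I the log2 ratio in covered bases was -0.27 and the permutation p was 0.13. With X as 1 chromosome among 6, an exact permutation of chromosomes cannot give a one-sided p below 0.17.

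**Figure D1:**
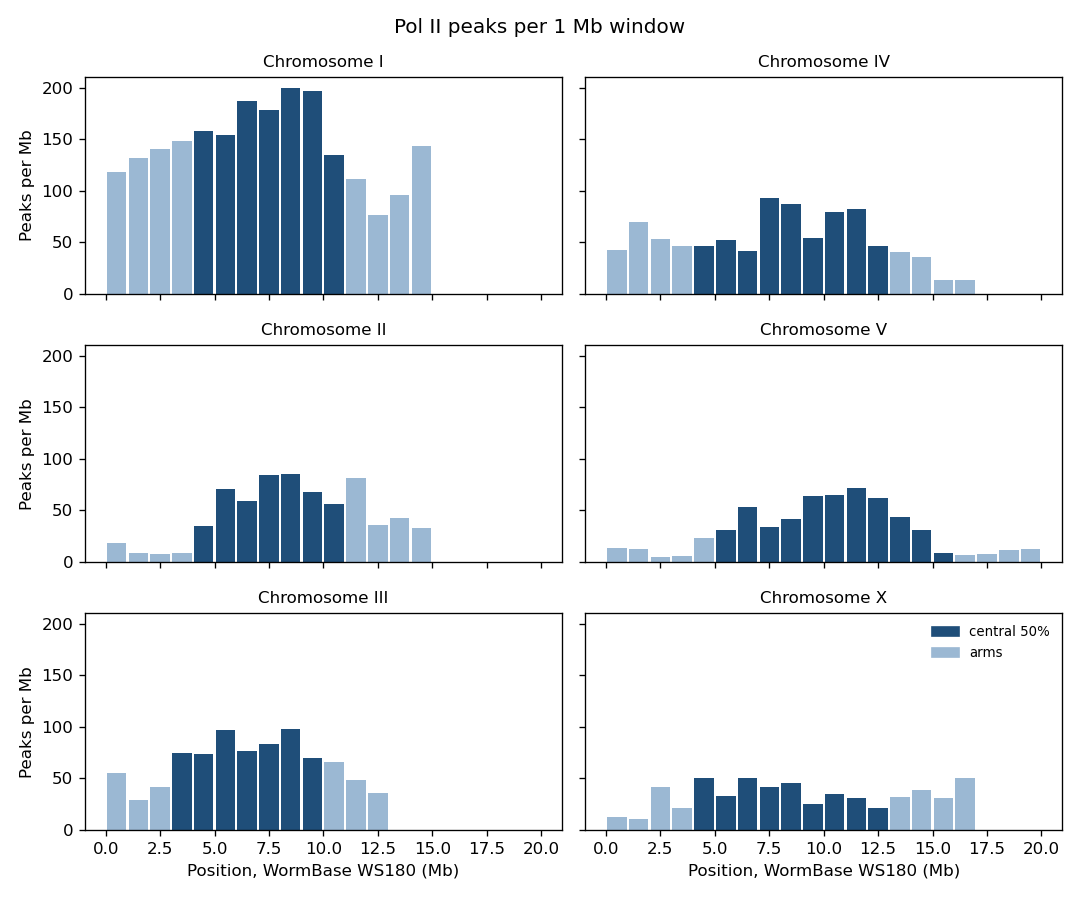
Number of Pol II peaks per 1 Mb window (y axis, by peak midpoint) along each chromosome (x axis, WS180 position in Mb); each bar is 1 full window, dark bars lie in the central 50% of the chromosome and light bars in its arms. Windows of chromosome I hold between 76 and 200 peaks, and those of the other chromosomes between 5 and 98.

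On the autosomes, Pol II peaks were denser in chromosome centres than in the arms. Worm autosomes have gene-dense centres and arms richer in repeats. The 41 central windows held 81.2 ± 47.3 peaks per Mb and the 39 arm windows 48.6 ± 42.9, a 1.67-fold difference (permutation p = 1e-05, the smallest possible). Covered bases differed alike, at 103.7 ± 24.2 against 61.6 ± 29.3 kb per Mb (1.68-fold, permutation p = 1e-05). When the profile of each chromosome was rotated, which keeps neighbouring windows together, the permutation p was 0.00056.

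The contrast was steepest on chromosome V, with 46.1 ± 19.1 peaks per Mb in the centre (11 windows) and 11.2 ± 5.56 in the arms (9 windows), 4.11-fold (exact permutation, adjusted p = 0.00078). It was 2.21-fold on II (exact permutation, adjusted p = 0.014), 1.78-fold on III (exact permutation, adjusted p = 0.0017), 1.64-fold on IV (exact permutation, adjusted p = 0.023) and 1.43-fold on I (exact permutation, adjusted p = 0.0032). These tests exchange windows freely within a chromosome, although neighbouring windows are not independent, so their p-values may be too small. The rotation was run on the autosomes together, not within single chromosomes. On X the centre had 37.0 ± 10.6 peaks per Mb (9 windows) and the arms 29.9 ± 13.9 (8 windows), a 1.24-fold difference within the spread between windows (exact permutation, adjusted p = 0.25). X thus had the smallest ratio of the 6 chromosomes, which chance gives with probability 0.17, and the difference from the autosomes was not tested beyond that.

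The longest stretches without a listed peak were in the arms of chromosomes V and II. On chromosome V they reached from 2905810 to 3701015 (795 kb), from 17118481 to 17904650 (786 kb) and from 1954205 to 2581981 (628 kb). On chromosome II the longest ran from 1535495 to 2192026 (657 kb). The longest on X was 447 kb, from 1591821 to 2039243. None of the 97 full windows was empty, so the longest run of windows with peaks was the 20 windows of chromosome V, and the window with the fewest peaks held 5.

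Wider peaks had smaller q-values. Across the 5942 peaks, which are not independent replicates, Spearman's rho between width and −log10 q was 0.62 (permutation p = 1e-05) and Pearson's r of the log values was 0.59 (permutation p = 1e-05). Within single chromosomes rho ranged from 0.64 on II and X to 0.72 on I. In a comparison added after the data were seen, −log10 q at equal width was higher on chromosome I than on every other chromosome in each of 6 bins of width between 50 and 7999 bp. Among peaks of 1000 to 1999 bp the median was 29.4 on chromosome I (258 peaks), and the medians of the other chromosomes lay between 7.18 on X (122 peaks) and 11.9 on III (140 peaks).

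**Figure D2:**
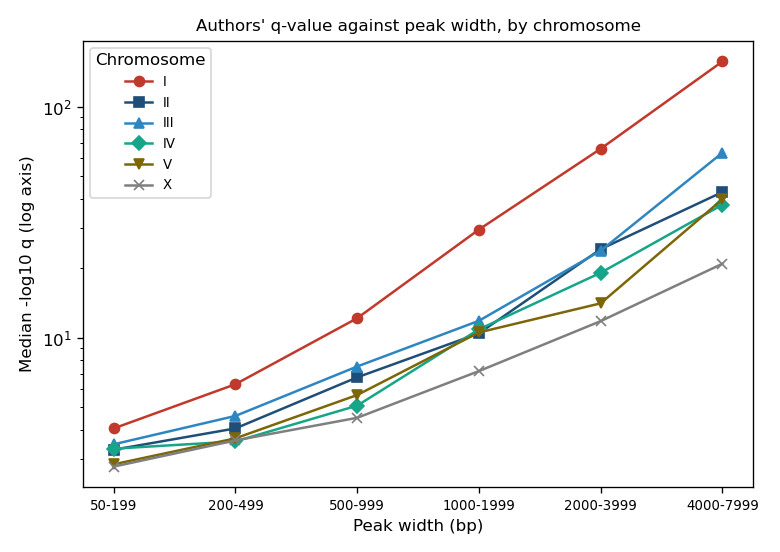
Median −log10 of the authors' q-value (y axis, log scale) for peaks in 6 bins of width (x axis, bp), with 1 line per chromosome. Chromosome I lies above the other chromosomes in each bin, for example at 29.4 against at most 11.9 for peaks of 1000 to 1999 bp.

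Pol II peaks were clustered at short range. Another peak lay within 1 kb of 39.0% of peaks, against 13.8% (95% of placements between 12.8% and 14.9%) when the same peaks were placed at random on their chromosomes. The placement p of this permutation test was 0.001, the smallest that it can give. Without chromosome I, the share was 29.0% against 8.08% at random. It was 56.3% on chromosome I, 33.3% on III, 33.2% on IV, 29.9% on II, 23.6% on X and 21.01% on V. These shares follow the order of peak density, and no random share was computed for single chromosomes. The ratio to random placement was 3.59 without chromosome I and 2.83 with it. Such a ratio has less room to rise where the random share is higher. These values therefore cannot tell whether clustering was stronger or weaker on chromosome I. Within 5 kb the share was 72.1%, against 54.1% at random, so the ratio to random placement was 2.83 at 1 kb and 1.33 at 5 kb. No listed peaks were closer than 200 bp, so these shares count peaks at least that far apart. Pieces of a single occupied stretch listed as separate peaks would also raise them, and this was not tested.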

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

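Of 51 recomputed values that could move, 47 kept their direction and their side of the 0.05 threshold. The alternatives for width against −log10 q and for spacing all had the smallest p that their tests can give. So did most of those for centre against arms and for chromosome I. Values so far from the threshold could hardly have crossed it, so the count says little about them. The 4 exceptions were chosen after the data were seen, and 3 of them concern the density of peaks on X. The log2 ratio of X to the autosomes was -0.48 without chromosome I, -0.27 for covered bases without chromosome I and -0.30 after peaks within 5 kb had been merged, with a largest permutation p of 0.13. In the first 2, the autosome with the most peaks is left out by construction. The cause of the third was not tested. The fourth is the bases covered on chromosome I against III alone, with a log2 ratio of 0.25 (permutation p = 0.11). The ratio of centre to arms ranged from 1.57-fold to 2.08-fold over the alternatives, and that of chromosome I to the other autosomes or to III alone from 1.19-fold to 3.59-fold. The ratio of observed to random spacing ranged from 1.33 with 5 kb as the limit to 3.59 without chromosome I. With all 95 regions of higher rank placed on X, its log2 ratio was -0.73, and with all of them placed in the arms the log2 ratio of centre to arms was 0.67. Merging peaks within 200 bp could move nothing, as the list has no such pair, and is not counted here. No paired analysis was possible because the list combines the libraries, and for the same reason no replicate could be left out. The planned comparisons with gene features, gene lists and GC content were not run, because no annotation of the list's build was used. Depth is unknown, so weak regions below the list's q limit cannot be judged.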

Other observations

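All tests in this part were chosen after the result was seen. Among the listed peaks, broad ones, of 5 kb or more, were sparsest on chromosome I, which had the most peaks in all. It held 1.8 ± 1.61 broad peaks per Mb (mean and SD over 15 windows). The means of the other chromosomes were 4.23 ± 2.24 on III, 3.73 ± 1.87 on II, 3.71 ± 1.31 on IV, 3.25 ± 2.07 on V and 3.06 ± 1.39 on X. These differences were not tested. The 95 regions of higher rank are not counted, and their widths and chromosomes are unknown. With only 27 listed broad peaks on chromosome I, such regions could change its place.

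On X, peaks had lower −log10 q than peaks of the same width on chromosomes II to V. X had the lowest median of the 6 chromosomes in 5 of the 6 bins of width. After the mean of each width bin had been subtracted, the log2 of −log10 q was -0.44 ± 0.33 over 17 windows of X and -0.14 ± 0.45 over 65 windows of II to V. The values are given as a description: X is 1 chromosome among 6, so a permutation of chromosomes cannot give a one-sided p below 0.17.

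The excess of peaks on chromosome I is the pattern that most calls for a second look. A few dense loci as the whole cause are argued against, since 93.3% of its windows (14 of 15) exceeded the 90th percentile of the other autosomes' windows. Weak calls near the threshold as the whole cause are argued against only as far as q measures strength. Peaks with q of 1e-20 or less were 3.47 times as dense there (permutation p = 1e-05). At equal width, however, q was itself smaller on chromosome I. The value therefore cannot set strong calls apart from weak ones whose q was lowered by more reads or a lower background. Longer occupied stretches split into pieces stay open: splitting adds no covered bases, and these were 1.43 times those of the pooled other autosomes (permutation p = 0.00034), which passed the bound first set against this explanation, but a second bound, against III alone, was added after that value was seen and was not passed (1.19-fold, permutation p = 0.11). Merging brought the ratio of peak numbers from 3.09 to 2.34 at 1 kb and to 1.52 at 5 kb. Both lay below the range that held 95% of random placements of the same peaks (2.78 to 2.87 and 1.74 to 1.85). Density thus gives a part of the fall. The rest goes with splitting as well as with loci that truly lie closer together. Peaks were also clustered without chromosome I, and random placement removes clustering everywhere, so the rest need not be particular to chromosome I. More reads or a lower background on chromosome I in the pooled libraries may also be the source: at equal width its median −log10 q was 1.17 to 2.72 times the highest of the other chromosomes in each of 6 bins, but a truly higher occupancy would give the same, and no biological explanation was tested.

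The start of the list at rank 96 is the other. The smallest recovered p-value was 1e-308, just below the smallest normal double-precision number (2.23e-308), and no rank was missing between the first and the last pair of equal p-values, at ranks 102 and 6030. P-values too small for double precision may have been lost at some step, and at which step is not known. The smallest recovered p-value is itself below the smallest normal double-precision number, so a cut exactly there would have removed it. Where a cut lay was not tested. Of the first 100 listed peaks, 34 were on chromosome I and 3 on X, which hold 36.7% and 10.2% of the whole list. The others were 18 on IV, 17 on V, 14 on II and 14 on III. Since the recovered ranks follow the p-values, the 95 regions would be those with the smallest p-values, whatever removed them. Rankings of single loci by q from this list therefore leave out the top regions. They need not have the strongest enrichment, for which the list holds no value.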
